A study of Drosophila melanogaster with 2 samples.

How the data were processed

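The series held chromatin immunoprecipitation sequencing (ChIP-seq) of the Drosophila melanogaster transcription factor foxo in whole wandering larvae of the last instar, of pooled sex. Per the labels, the flies carried a transgene for foxo fused at its C-terminus to enhanced green fluorescent protein, chromatin was sheared by sonication with a stated size range of 200 to 800, whose unit the labels do not give, and the precipitation used an antibody against the fluorescent protein, although another label field names foxo itself as the target of the antibody. There were 2 biological replicates, numbered 5 and 6 in the labels, and both belonged to 1 group. No other genotype, stage or treatment was compared. A control library was named as an input to the authors' processing per the labels, and it was not analysed here.

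The authors deposited interval lists. Per the notes deposited with each sample, each replicate had a relaxed list of peaks and background made from its alignments and a control. A pooled relaxed list was made as well. Per the same notes, a thresholded list came from comparing the replicate lists with the pooled list by irreproducible discovery rate (IDR). That method sets a threshold from how alike replicates rank regions. The aligner, the peak caller and their versions were not given in the sources used here. The deposited peak signal was the value of the authors' caller for each region, on a scale that is not stated, and it was used only to rank, describe and correlate regions, since lists of different depth need not share a scale. The deposited significance column held −log10 of a q-value, and the deposited p-value column held no values. The summit was the deposited offset within each interval. Per the labels, the reads were processed on the dm6 and dm3 assemblies. The dm6 lists were analysed, and of the dm3 lists only the number of IDR peaks was used, because a dm3 genome was not used here. Read numbers were unknown, so no depth per library can be given. Each relaxed dm6 list held 30000 regions whatever its library, so the number of regions says nothing of depth. Intervals below cover counting error over peaks or genes only.

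Coordinates are 1-based on dm6. Its chromosome lengths in the reference genome (Release 6 assembly) covered the highest region end on each of the 6 chromosomes X, 2L, 2R, 3L, 3R and 4. Genes, transcripts and transcription start sites (TSSs) came from Ensembl release 115, with transposable elements left out, giving 18164 genes on those chromosomes, of which 13945 were protein-coding, and 23581 distinct TSS positions. A summit was assigned in this order to within 500 bp of a TSS, 5′ UTR, 3′ UTR, coding sequence, non-coding exon, intron or intergenic sequence.

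An IDR peak counted as recovered in a replicate when its summit lay within 150 bp of a summit among that replicate's 1427 regions of highest signal, 1427 being the number of IDR peaks. Chance recovery came from 100 random placements of the summits on their own chromosomes. Signals were compared on a log10 scale across IDR peaks, with 100000 permutations, and peaks are not independent replicates. The promoter share and the X share were tested with exact two-sided binomial tests against the share of bases within 500 bp of a TSS and the X share of TSS positions. Consensus sequences on either strand were counted within 100 bp of summits and in windows of equal width centred 1000 bp to each side, leaving out flanks that touched any IDR peak (for a single replicate, any of its own regions used). Each summit was paired with 1 flank drawn with a fixed seed for an exact two-sided McNemar test, and 13 consensus sequences were adjusted together by Benjamini-Hochberg. All 7-mers within 50 bp of summits were compared with the flanks by Fisher's exact test. A gene had a promoter peak when an IDR summit lay within 1000 bp of any of its TSSs. Then 23 gene lists were tested with two-sided Fisher's exact tests against all other protein-coding genes and adjusted by Benjamini-Hochberg. Of the list members asked for, 2 did not match the annotation. The p-values treat peaks or genes as the units and measure no variation between animals.

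Genes were named by a rule: the gene with the TSS nearest to each of the 15 IDR peaks of highest signal; foxo, InR, Thor and Akt in any case; and up to 4 members of highest signal from the insulin and TOR list and each list above the other genes, or up to 2 from each list below. The lists, tests, naming rule and most alternatives were fixed before the data were examined. The alternatives were the 713 IDR peaks of highest signal, each replicate's own 1427 highest regions in place of the IDR list, other distances, windows and flanks, promoter or distal peaks alone, other motif spellings, 10000 random gene lists matched on number of TSSs and gene length, a background of genes with any pooled relaxed region within 1000 bp, and the dm3 count. Added after seeing the data were 100 other draws of the flanks, the 356 peaks of highest signal, correlation over all pooled regions, and gene lists without the foxo locus.

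The tests were checked on simulated data. At 1427 random sites the FOXO consensus gave a ratio of 1.16 (exact McNemar p = 0.358) and no 7-mer was called. With the consensus planted in 9.95% of the sites, the share rose by 9.53 percentage points and the planted 7-mer ranked first. Of 100 random gene lists from 13945 genes, 0 were called. The simulated sites lay at random positions, and simulated peaks were given to genes independently of one another. The check therefore does not cover effects of promoter position, summit base composition, number of TSSs or gene length. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.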

Results

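Binding of the forkhead transcription factor foxo, a nuclear effector that insulin signalling restrains through the kinase Akt, was mapped by ChIP-seq in whole wandering larvae, the stage at which feeding ends before pupariation. The larvae carried a green fluorescent protein fusion of foxo that was precipitated through its tag. The data comprised 2 biological replicates of 1 group, so the comparisons are between sites, sequences and gene groups and not between conditions. The IDR list held 1427 peaks on dm6 with authors' signals of 69.0 to 745 and a median width of 380 bp, and 1377 peaks on dm3. The dm6 IDR list was identical to the 1427 regions of highest signal in the pooled list. A place in it therefore followed pooled signal and does not show that a given peak ranked alike in both replicates. Library depth was unknown. The replicate lists each held 30000 regions, of which 1061 in replicate 5 and 6870 in replicate 6 had a q-value of at most 0.01.

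The top regions of both replicates held 626 of the 1427 IDR peaks (43.9%), and signals at matched peaks were only weakly correlated. Of the 1427 IDR peaks, 977 (68.5%, 95% Clopper-Pearson interval 66.0 to 70.9) had a summit within 150 bp among the top regions of replicate 5, and 987 (69.2%, 66.7 to 71.6) among those of replicate 6. Random placement recovered 0.317% and 0.308% on average, but the IDR peaks were the highest regions of the pool of these same replicates, so recovery above random in each was set by construction. The top regions of neither replicate held 89 peaks (6.24%). Across the 1324 peaks matched in both lists, signals correlated with a Spearman's rho of 0.18 (permutation p = 1e-05) and a Pearson's r of 0.31 on log10 values (permutation p = 1e-05), the smallest p that the permutations can give. Peaks were selected on their pooled signal, which removes sites low in both replicates. Over the 9444 pooled regions matched in both lists, an extent added after seeing the data, rho was 0.47.

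**Figure D1:**
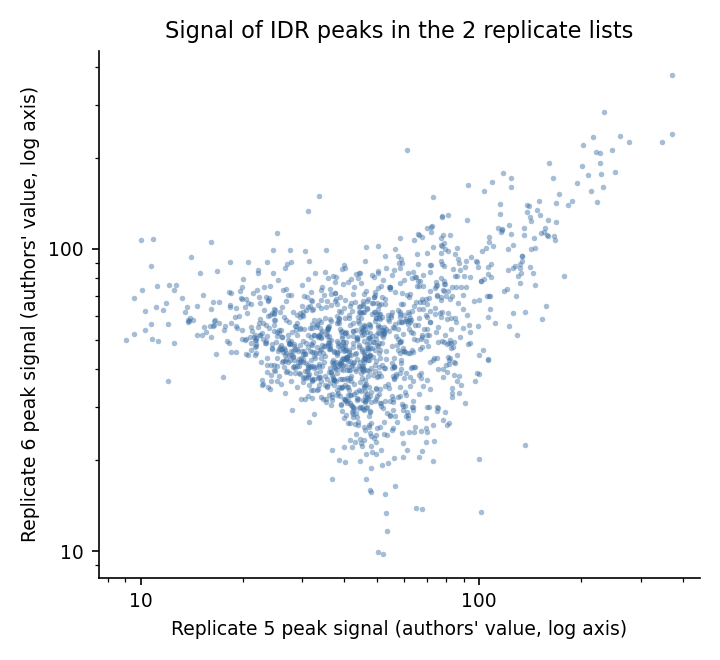
Each point is 1 of the 1324 IDR peaks matched in both lists, with its authors' signal in replicate 5 (horizontal) and replicate 6 (vertical), both on log axes. The highest peaks are high in both replicates, the empty lower left corner follows from the selection on pooled signal, and rho across the points is 0.18.

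Foxo peaks were more frequent near promoters than the share of bases there. Of the 1427 summits, 740 (51.9%, 95% Clopper-Pearson interval 49.2 to 54.5) were within 500 bp of a TSS, against 13.6% of bases, a 3.83-fold excess (exact binomial p = 5.85e-259). Of those 740 summits, 590 (79.7%) lay upstream of the nearest TSS (exact binomial p = 1.14e-63 against equal shares). Beyond 500 bp of a TSS, introns held 508 summits (35.6% against 39.5% of bases) and intergenic sequence 136 (9.53% against 27.2%). Coding sequence beyond 500 bp of a TSS and outside UTRs held a single summit (0.0701%) although it made up 13.1% of bases (exact binomial, adjusted p = 1.60e-84 over 7 classes). Summits in coding sequence nearer to a TSS were counted in the first class. The median distance to a TSS was 424 bp, and 148 summits (10.4%) were over 5000 bp away. Peaks within 500 bp of a TSS and peaks beyond had median signals of 90.4 and 90.7, a difference that did not pass the test (permutation p = 0.913).

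**Figure D2:**
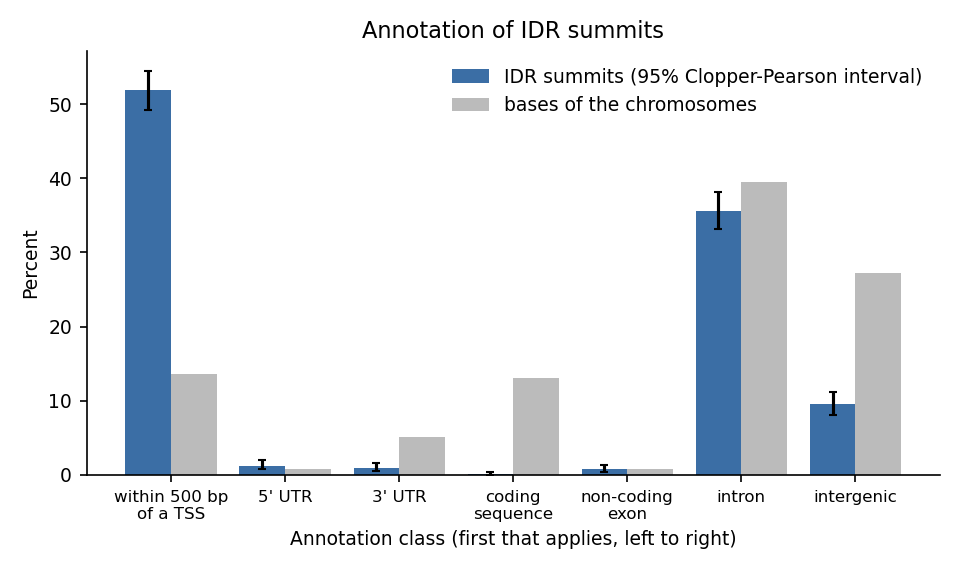
Share of the 1427 IDR summits (blue, with 95% Clopper-Pearson intervals) and of the bases of the 6 chromosomes (grey) in each annotation class, in percent. Summits exceed bases within 500 bp of a TSS (51.9% against 13.6%). They fall below them in coding sequence beyond 500 bp of a TSS and outside UTRs (0.0701% against 13.1%).

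The highest peaks lay at genes of varied function. The highest of all (signal 745, 2L, 6612446 to 6612871) was in an intron of CG11050 and ranked first in both replicates. Next came peaks 36 bp upstream of a TSS of Ugalt, a UDP-galactose transporter (609, X, 2703729 to 2704037), and 98 bp upstream of CG14100 (570, 3L, 19590461 to 19590760). A peak of 481 lay 69 bp downstream of a TSS of PNPase, the polynucleotide phosphorylase of mitochondria (3R, 31404530 to 31404798). The peak nearest to cbt, a zinc finger transcription factor, had a signal of 464 and lay 1412 bp upstream of it in an intron of ush (2L, 480942 to 481249). Peaks at ph-p, a Polycomb group gene (408, X, 2137203 to 2137486), and Chro, which encodes the chromosomal protein Chromator (399, 3L, 22878762 to 22879033), were within 500 bp of a TSS. The remaining peaks among the 15 highest were nearest to CG1888, CG18549, lncRNA:CR31044, CG9147, CG16753, CenG1A, CG32772 and lncRNA:CR46035. All 15 stood among the first 18 regions of replicate 5 and the first 26 of replicate 6. None of the 15 had the FOXO consensus within 100 bp of its summit. Its share among all IDR peaks was 6.52%, so its absence from 15 peaks does not show a lower share.

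The consensus TGTTTAC, the core of the element that FOXO proteins bind, was present near a small share of peaks. It lay within 100 bp of 93 summits (6.52%, 95% Clopper-Pearson interval 5.29 to 7.92) and in 3.92% of flanks, a ratio of 1.66 (exact McNemar p = 0.00808). Among the 210 orderings of the same bases, 10 including TGTTTAC itself had a ratio as high (share 0.0476, 95% bootstrap interval 0.019 to 0.371), and the median ratio was 1.17. Peaks with the consensus had a median signal of 88.8 and those without it 90.7 (permutation p = 0.605). The excess did not pass the test with flanks at 500 bp (ratio 1.34, exact McNemar p = 0.264) or 2000 bp (1.39, exact McNemar p = 0.135), among the 713 highest peaks (1.79, exact McNemar p = 0.0533) or the 356 highest (2.07, exact McNemar p = 0.073), among peaks beyond 500 bp of a TSS (1.60, exact McNemar p = 0.336), or for the longer TTGTTTAC (1.63, exact McNemar p = 0.101). In 100 other draws of the flanks at 1000 bp, chosen after seeing the data, the exact McNemar p was at most 0.0382, and over the other windows, flanks and peak sets tried for TGTTTAC itself the exact McNemar p ran from 4.27e-05 to 0.336.

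Of the 13 consensus sequences, the GAGA element had the lowest p-value in the IDR list, but not in replicate 5 alone. GAGAGAG, bound by the GAGA factor Trl, was near 188 summits (13.2%, 95% Clopper-Pearson interval 11.5 to 15.04) and in 4.10% of flanks, a ratio of 3.21 (exact McNemar, adjusted p = 2.28e-16). The ratio was 1.68 in the top regions of replicate 5 (exact McNemar, adjusted p = 0.0209) and 4.89 in those of replicate 6 (exact McNemar, adjusted p = 8.86e-36). In replicate 5 RYAAAYA had the lowest p (exact McNemar, adjusted p = 2.16e-11). The general forkhead consensus RYAAAYA was near 52.1% of summits and in 41.1% of flanks (ratio 1.27, exact McNemar, adjusted p = 2.91e-08). It is rich in A and includes TGTTTAC read on the other strand, so the 2 tests are not separate. Mean GC content was 38.8% at summits and 42.7% in flanks. Other orderings of its bases were not compared, so composition cannot be told apart from a preference for RYAAAYA. The DNA replication-related element TATCGATA was near 34 summits (2.38%) and in 0.805% of flanks (ratio 2.96, exact McNemar, adjusted p = 0.0305), and the FOXO core had the same adjusted p. The GATA sequence TGATAAG was at 5.47% against 3.88% and the ecdysone receptor site AGGTCA lower at 3.08% against 4.90% (both exact McNemar, adjusted p = 0.0364). These last calls depended on the flank drawn, since TGATAAG passed in 25 of 100 draws and AGGTCA in 60, and TGATAAG did not pass in either replicate alone (ratio 1.10 in both) or among the 713 highest peaks (0.969). AGGTCA passed in replicate 6 alone (ratio 0.512, exact McNemar, adjusted p = 0.00016) and not in replicate 5 alone (0.654, exact McNemar, adjusted p = 0.101). Among those 713 peaks the TATCGATA, TGTTTAC and AGGTCA calls were lost too (exact McNemar, adjusted p = 0.6, 0.231 and 0.255), with fewer pairs and ratios of 2.70, 1.79 and 0.661. Sequences that did not pass were the STAT site TTCNNNGAA at 4.84% against 6.66%, GGTCACACT of M1BP at 0.631% against 0.256%, the Myc E-box CACGTG at 2.24% against 2.71%, the AP-1 site TGASTCA at 2.17% against 2.12%, the CREB site TGACGTCA at 0.631% against 0.512%, the Zelda-like CAGGTAG at 1.12% against 1.46% and the homeodomain site TAATTA at 13.3% against 11.9% (exact McNemar, adjusted p from 0.0563 to 0.625). Of these, TTCNNNGAA passed as lower in replicate 5 alone (ratio 0.643, exact McNemar, adjusted p = 0.0234) and within 200 bp (0.734, exact McNemar, adjusted p = 0.00543), and GGTCACACT as higher within 200 bp (2.42, exact McNemar, adjusted p = 0.0142). Within 50 bp the TATCGATA, TGATAAG and AGGTCA calls were lost, at ratios of 1.93, 1.28 and 0.701 (exact McNemar, adjusted p = 0.425, 0.31 and 0.182). The TGATAAG call was also lost within 200 bp (1.29, exact McNemar, adjusted p = 0.083).

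**Figure D3:**
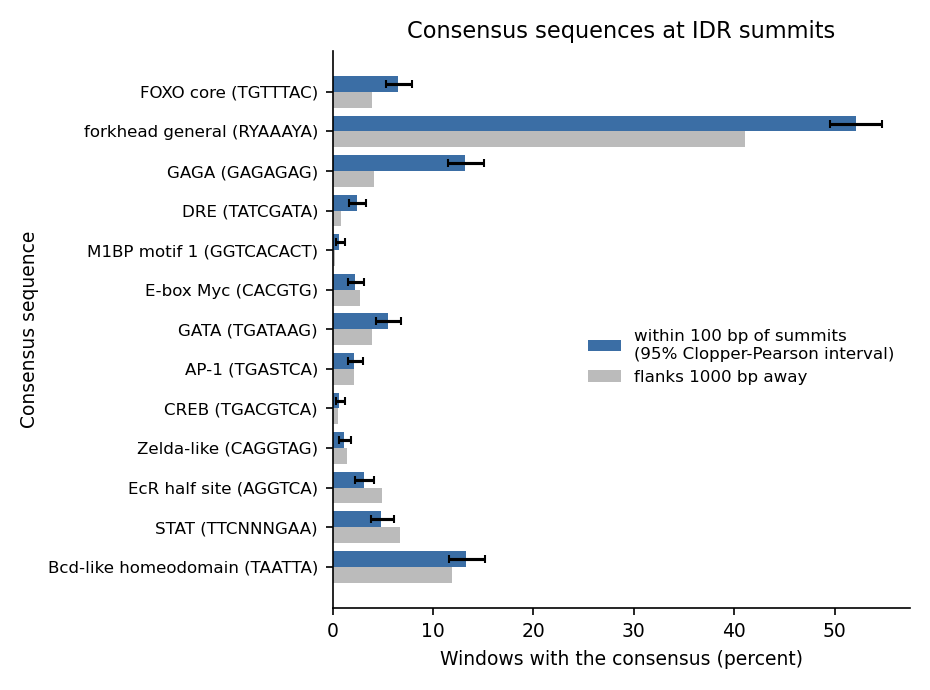
Percent of windows holding each of 13 consensus sequences within 100 bp of the 1427 IDR summits (blue, with 95% Clopper-Pearson intervals) and in flanks 1000 bp away (grey). GAGAGAG is at 13.2% against 4.10% and TGTTTAC at 6.52% against 3.92%.

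Without a preset consensus, 205 of 8192 7-mers were more frequent within 50 bp of summits than in flanks and 222 were less frequent. A/T-rich words led, with AAAATAA at 16.0% of summits and 7.68% of flanks (exact Fisher, adjusted p = 5.99e-12), followed by words of the GAGA type such as CGCTCTC at 6.17% against 1.88% (exact Fisher, adjusted p = 6.03e-09). The enriched words comprised 42 made only of A and T and 20 with a GA repeat. These counts were 13 and 41 without replicate 5, and 39 and 2 without replicate 6. The FOXO core was among them at 3.57% against 1.74% (exact Fisher, adjusted p = 0.0136). The depleted word with the lowest p was CACCTCC, found at 0 summits and 1.38% of flanks (exact Fisher, adjusted p = 7.56e-05). Windows of 100 bp to each side had a mean GC content of 38.8% at summits and 42.7% in flanks, and the scan does not correct for it. Among peaks beyond 500 bp of a TSS 23 words were enriched and 1 depleted, among the 713 highest peaks 71 and 17, and without replicate 5 114 and 65.

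Genes of insulin and TOR signalling, the pathway upstream and downstream of foxo, carried promoter peaks more often than other genes. An IDR summit lay within 1000 bp of a TSS for 10 of 32 members (31.3%, 95% Clopper-Pearson interval 16.1 to 50.01) and for 1065 of 13913 other protein-coding genes (7.65%, exact Fisher, adjusted p = 0.000731). The highest of these peaks was at Sesn, the sestrin gene (signal 213, 226 bp upstream, 2R, 23713586 to 23713752), followed by alc, the AMPK beta subunit (153, 982 bp upstream within CG44286 and CG8788, 2R, 9138725 to 9139104), Pdk1, a kinase that activates Akt (114, 959 bp upstream in intergenic sequence, 3L, 128301 to 128680), and foxo itself (108, 101 bp upstream, 3R, 14056654 to 14057033). Thor, the 4E-BP gene, had a peak of 90.0 at 69 bp upstream (2L, 3478175 to 3478554), the insulin receptor gene InR of 83.5 at 18 bp upstream (3R, 21619149 to 21619528), and Akt of 75.1 within its own intron, 715 bp from its nearest TSS (3R, 16099855 to 16100234). Pi3K21B, REPTOR and scyl, named outside the rule after their values were seen, completed the 10, of which 7 had the summit within 500 bp of the gene's own TSS. The InR peak ranked 297 in replicate 6 and 6656 in replicate 5, the scyl peak 339 and 13864, and the Pi3K21B peak 2898 and 335. The Akt peak had no region within 150 bp in replicate 5. Each replicate's own top regions marked 10 members, of which 7 in replicate 5 and 8 in replicate 6 also had an IDR peak. Random lists matched on number of TSSs and gene length held 4.50 genes with a peak on average (permutation, adjusted p = 0.0589), and the adjusted p over all 8 alternatives, by exact Fisher or permutation test, ran from 0.000544 to 0.0589.

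Cytoplasmic ribosomal protein genes carried promoter peaks more often than other genes. Of 92 members, 26 had a promoter peak (28.3%, 95% Clopper-Pearson interval 19.4 to 38.6) against 7.57% of other genes (exact Fisher, adjusted p = 7.92e-08), where matched random lists held 7.02 (permutation, adjusted p = 0.0023). Over the 8 alternatives the adjusted p, by exact Fisher or permutation test, was at most 0.0186. The summit was within 500 bp of the gene's own TSS in 25 of the 26, at a median of 53 bp. RpL14 (signal 139, 3L, 8600732 to 8601111), RpL32 (139, 3R, 30046288 to 30046437), RpS27 (129, 3R, 25247328 to 25247707) and RpL19 (116, 2R, 24969420 to 24969799) had the highest. Top regions of replicate 5 marked 27 members and those of replicate 6 marked 20. None of the 26 peaks had the FOXO core within 100 bp of the summit, and of the 10 insulin and TOR peaks 1 had it. That was the Akt peak, which had no region within 150 bp in replicate 5. Of all IDR peaks 6.52% had the core, so in groups this small these counts do not show a different share. GAGAGAG was also near none of the 26 ribosomal protein summits, against 13.2% of all IDR summits, a difference that was not tested. The random lists were not matched on expression or accessibility, and no signal from an untagged strain was analysed here. General accessibility of the promoters therefore stays open for this and the other lists.

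Stress, ecdysone and metabolic genes also carried promoter peaks more often than other genes. In the heat and oxidative stress list, 8 of 35 members had one (22.9%, exact Fisher, adjusted p = 0.0201), led by the small heat shock gene Hsp27 (signal 274, 123 bp upstream, 3L, 9383779 to 9384036), the Hsp90 gene Hsp83 (151), the catalase gene Cat (139) and Keap1, the inhibitor of the oxidative stress factor cnc (134). In the ecdysone list, 7 of 29 had one (24.1%, exact Fisher, adjusted p = 0.0211), led by the coactivator gene tai (179), Ldh (146), the ecdysone receptor gene EcR (143, 2R, 6131966 to 6132345) and the nuclear receptor gene Eip75B (119). In the lipid and sugar list, 7 of 33 had one (21.2%, exact Fisher, adjusted p = 0.0377), led by Lpin, a phosphatidate phosphatase gene (216, 2R, 8146131 to 8146352), the glycogen phosphorylase gene Glyp (123), the hexokinase gene Hex-A (120) and the trehalase gene Treh (86.7). Glyp, Hex-A and Treh ranked 179, 168 and 372 in replicate 5 and 1479, 2330 and 3219 in replicate 6, and the Keap1 peak had no region within 150 bp in replicate 6. The Keap1 summit lay 810 bp upstream of that gene, in an intron of kuk. The Treh summit lay 944 bp upstream of Treh and within 500 bp of a TSS of another gene. Against matched random lists these calls were lost, with permutation adjusted p = 0.166 for stress, 0.507 for ecdysone and 0.752 for lipid and sugar; the lowest adjusted p over the 8 alternatives of each, by exact Fisher test, were 0.000899, 0.00215 and 0.0351. With a single replicate's own regions, the ecdysone call was lost without replicate 5 (exact Fisher, adjusted p = 0.0572), and the stress and the lipid and sugar calls without replicate 6 (exact Fisher, adjusted p = 0.0507 and 0.108).

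Chemoreceptor and cuticle protein genes lacked promoter peaks. None of 179 chemoreceptor genes had one, which allows a share of up to 1.68% as 3 counts of the total, with a 95% Clopper-Pearson limit of 2.04% (exact Fisher, adjusted p = 1.46e-05), nor did any of 118 cuticle protein genes, which allows up to 2.54% on the same basis, with a Clopper-Pearson limit of 3.08% (exact Fisher, adjusted p = 0.000925). The cuticle call, still at 0 of 118, was lost among the 713 highest peaks (exact Fisher, adjusted p = 0.0589). With a background of the 8132 genes that had a pooled relaxed region at a TSS, 0 of 38 chemoreceptor and 0 of 29 cuticle protein genes had a promoter peak, against 13.3% of the others for each, and with these smaller sets neither call passed (exact Fisher, adjusted p = 0.055 and 0.144), nor did the stress, ecdysone or lipid and sugar calls (exact Fisher, adjusted p from 0.144 to 0.304).

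The other lists did not pass. The growth and cell cycle list had 4 of 17 members with a promoter peak (exact Fisher, adjusted p = 0.107). With a summit within 5000 bp or in the gene body it had 10 of 17, against 17.1% of other genes (exact Fisher, adjusted p = 0.000984). That wider count was not matched on gene length. For promoter peaks, random lists matched on number of TSSs and gene length held 2.23 (permutation, adjusted p = 0.735). The JNK, JAK-STAT and apoptosis list had 5 of 26 (exact Fisher, adjusted p = 0.117), where matched random lists held 3.04 (permutation, adjusted p = 0.735). In replicate 6's own regions, without replicate 5, it had 8 of 26 (exact Fisher, adjusted p = 0.00188). Mitochondrial ribosomal proteins had 9 of 73 (exact Fisher, adjusted p = 0.414), and they passed against matched lists, which held 3.02 (permutation, adjusted p = 0.0291), and within 5000 bp or in the gene body (exact Fisher, adjusted p = 0.0237). The highest of the 9 peaks (signal 424) lay 404 bp upstream of mRpS23 and was the peak nearest to CenG1A, 88 bp upstream of that gene. The mRpL2, mRpL51 and mRpS31 summits lay within FoxK, Uba4 and hzg. These genes were named outside the rule after their values were seen, and the matching did not cover promoters shared with a neighbour. Oxidative phosphorylation had 5 of 84, proteasome 2 of 48, autophagy 1 of 25, antimicrobial peptides and immune regulators 2 of 21, disc and segment patterning 1 of 35 and the insulin-like peptides 0 of 8, which allows up to 37.5%. Among tissue markers, muscle had 2 of 25, neurons 2 of 19, salivary glands 2 of 14, midgut 1 of 32, haemocytes 1 of 14, testis 1 of 27 and fat body 0 of 11, which allows up to 27.3%. The exact Fisher adjusted p of these lists ran from 0.616 to 1. In all, 1075 protein-coding genes had a promoter peak.

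**Figure D4:**
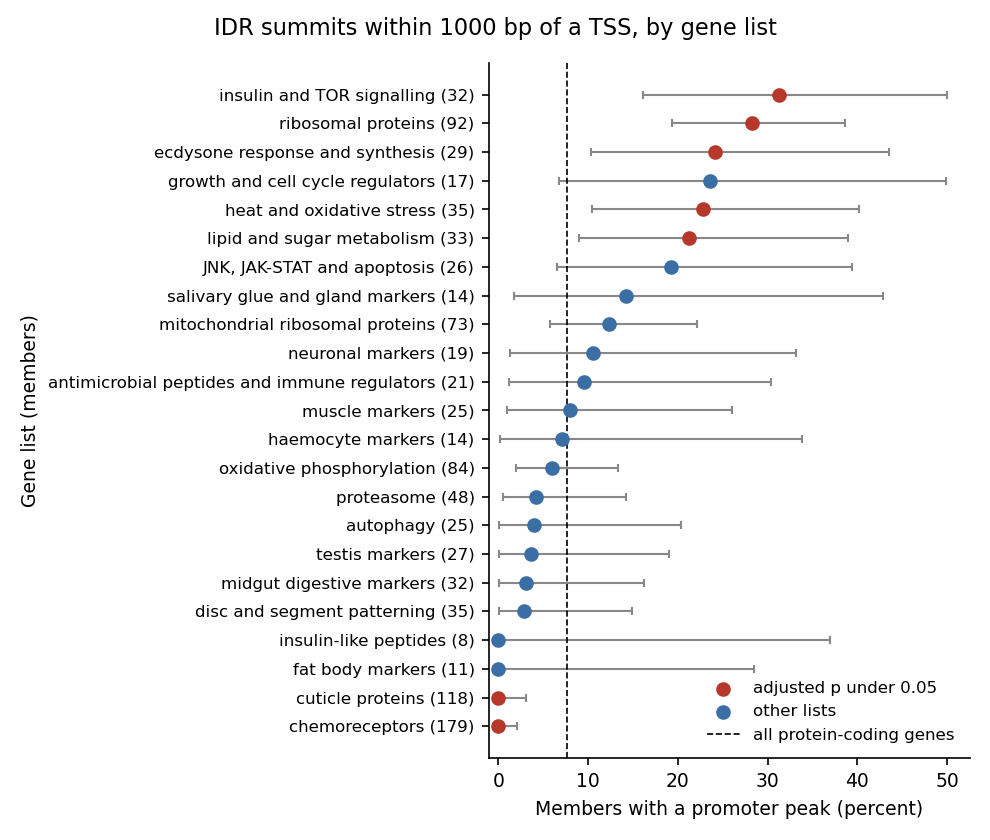
Percent of each list's members with an IDR summit within 1000 bp of a TSS (points, with 95% Clopper-Pearson intervals; members in brackets), with the share of all protein-coding genes as a dashed line. Red marks the 7 lists with an adjusted p under 0.05, from insulin and TOR signalling at 31.3% to chemoreceptors at 0.

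The X chromosome held 205 summits (14.4%, 95% Clopper-Pearson interval 12.6 to 16.3) against 16.6% of TSS positions (exact binomial p = 0.0249), and adjusted over the 6 chromosomes this did not pass (exact binomial, adjusted p = 0.0746). The shares in single replicates lay on both sides of that value, at 13.0% in the top regions of replicate 6 and 17.0% in those of replicate 5 (exact binomial p = 0.000182 and 0.643). Among the 713 highest peaks the X share was 16.0% (exact binomial p = 0.724).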

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

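The draws of the flanks, the 356 highest peaks, the correlation over all pooled regions and the lists without the foxo locus were chosen after seeing the data. The promoter excess, the signal correlation and the ribosomal protein and GAGA calls kept their direction and their side of the threshold under every alternative run for them. The promoter share ranged from 37.98% within 200 bp to 65.0% within 1000 bp. The dm3 list had 1377 peaks. Peak recovery followed the definition by construction: with the 713 highest peaks it was 87.8% in replicate 5 and 86.0% in replicate 6, within 50 bp 57.2% and 57.0%, with 2854 regions 81.9% and 88.2%, and over all regions 94.1% and 98.7%. The FOXO core ratio stayed above 1 and lost its call with flanks at 500 bp (1.34) and 2000 bp (1.39), among the 713 (1.79) or 356 (2.07) highest peaks, in distal peaks (1.60) and as TTGTTTAC (1.63); smaller sets have fewer pairs to test, and for the flanks the cause was not tested. With other draws of the flanks the exact McNemar p was under 0.05 in 35, 39, 80 and 48 of 100 draws for flanks at 500 bp, at 2000 bp, the 713 peaks and distal peaks. Of the 13 sequences, 6 passed in the main test, 2 among the 713 peaks, 3 within 50 bp, 7 within 200 bp, 5 without each replicate and from 3 to 8 over the 100 draws. TGATAAG turned to a ratio of 0.969 among the 713 peaks. Enriched 7-mers fell from 205 to 71 among the 713 peaks and 23 in distal peaks, with fewer windows, and ran from 114 to 232 without each replicate. Genes with a promoter peak numbered 548 for the 713 peaks and 2388 within 5000 bp or in the gene body, both by construction. Of all 23 lists, 7 passed in the main test, 4 with matched random lists (3 of the 7 and mitochondrial ribosomal proteins), 2 with the relaxed-region background and 7 without the foxo locus. The lipid and sugar call was lost under 6 alternatives, the ecdysone call under 4, the stress call under 3, the cuticle call under 2, the chemoreceptor and the insulin and TOR calls under 1 each and the ribosomal protein call under 0. The X share, lower in the main list only before adjustment over the 6 chromosomes, was 16.0% among the 713 peaks and not called there. It ran from 13.0% to 17.0% without each replicate, where the cause was not tested. The signal difference of peaks with the FOXO core ran from -0.0383 to 0.0117 (log10) without each replicate, and passed without replicate 6 alone (permutation p = 0.0282). No paired analysis was possible because there was a single group. The unknown read depth limits what the lists can show of weak sites.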

Other observations

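The comparisons of biotypes, chromosomes, genes with several peaks, motif positions and replicate GAGA shares were chosen after the results had been seen. So were the list of chromatin regulators, both tests on windows around foxo, the draws of the flanks and the bootstrap interval of the anagram share. Several large genes carried clusters of foxo peaks within the gene body. Eip75B, an ecdysone-induced nuclear receptor gene, had 10 IDR summits in 113744 bp (0.879 per 10 kb), against 0.101 per 10 kb over all protein-coding gene bodies. Raf, the MAP kinase kinase kinase gene, and bun had 9 each, and shn, Eip74EF and ush had 7 each. InR had 5 and foxo 4. In all 65 genes had at least 3. Chromosome 4 held 3 of the 1427 IDR summits and 477 of the 30000 pooled relaxed regions (exact Fisher, adjusted p = 2.07e-06), while against its 0.776% of TSS positions its 0.210% of summits did not pass (exact binomial, adjusted p = 0.0564). Among biotypes, 7.71% of protein-coding genes and 4.42% of non-coding RNA genes had a summit within 1000 bp of a TSS, as did 16 of 290 tRNA genes and 0 of 99 ribosomal RNA genes. TATCGATA was at 4.46% of the 740 promoter peaks and 0.146% of the 687 distal ones (exact Fisher, adjusted p = 6.66e-08), and CACGTG at 3.24% and 1.16% (exact Fisher, adjusted p = 0.0482). By contrast, TGATAAG was at 3.92% and 7.13% (exact Fisher, adjusted p = 0.0482). TGTTTAC was at 6.76% and 6.26% and did not differ by the test (exact Fisher, adjusted p = 0.791).

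Chromatin regulators such as ph-p, Chro, Trl, psq, trx and Sin3A stood among the genes with the highest peak or with several peaks. The hypothesis that genes of this kind carry promoter peaks as a group was tested on a list of Polycomb, trithorax and other chromatin regulators, leaving out every gene already named or with at least 3 summits. Of the remaining 44 members, 10 had a promoter peak (22.7%, 95% Clopper-Pearson interval 11.5 to 37.8), against 7.11% of 13807 other genes (exact Fisher p = 0.000895). Matched random lists held 4.08 (permutation p = 0.0094). The members with a peak, named after their values were seen, were BEAF-32, Cp190, Kdm2, Su(var)205, Utx, brm, mod(mdg4), mor, nej and ph-d. The hypothesis may hold for these peaks, and no signal from an untagged strain was analysed here, so general accessibility of such promoters stays open.

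The GAGA sequence separated the replicates. It was within 100 bp of 269 of the 1427 top regions of replicate 6 (18.9%) and of 109 of those of replicate 5 (7.64%), a difference of 11.2 percentage points (exact Fisher p = 5.62e-19). GC content over 500 bp was 42.7% and 40.3%. At equal GC over 500 bp the difference was 10.05 points (95% bootstrap interval 7.27 to 12.7). This argues against GC content at that width as the whole cause. Within 100 bp of the summits GC content was 41.3% in replicate 6 and 37.4% in replicate 5, and it was not equalised at that width. Weaker regions at the foot of a list do not account for the GAGA difference, since among the 300 highest regions the shares were 20% and 6.33% (exact Fisher p = 8.44e-07). Differences in precipitation or library preparation may remain, and no biological explanation was tested because the design names no difference between the replicates.

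The excess of the FOXO core at summits may be partly a matter of base composition, since summits are richer in A and T than flanks. Of the 210 anagrams of TGTTTAC, a share of 0.0476 had a ratio as high, under the bound of 0.05 set beforehand. Its bootstrap interval of 0.019 to 0.371 spans that bound, so composition cannot be told apart from a preference for the sequence. Promoter sequence next to gene sequence stays open as well, because peaks beyond 500 bp of a TSS had a ratio of 1.60 that passed in 48 of 100 draws of the flanks and is limited by 687 peaks. No biological explanation was tested against these.

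The foxo locus itself held 6 IDR summits in the gene and 20 kb to each side, more than 99.0% of 1000 windows of 71034 bp around other genes, which had a median of 1. Extra copies of the locus on the transgene could raise counts there, and below-threshold regions also stood high, at 46 against a median of 19 (percentile 99.1). Windows around other genes with at least as many IDR peaks, 10 in number, held 29 to 53 such regions, so a locus dense in regions of every height is also a possible explanation. Both fit the counts, the extent of the transgene is not given in the sources used here, and autoregulation of foxo was not tested. High counts were not confined to the window. Just outside it on 3R, 14016945 to 14026944 held 3 IDR summits and 7 below-threshold regions, and 14026945 to 14036944 held 1 and 8. That stretch overlaps rdx, which had 5 IDR summits in its gene body, against 4 for foxo. At the other end of the window, 14096945 to 14106944 held 0 and 2.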
